A study of Homo sapiens with 6 samples.

How the data were processed

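The data are RNA-seq libraries of A375 melanoma cells that express EosFP, 3 from extravasating cells and 3 from control cells, and each library's group was taken from its sample type in the labels. Per the labels, total RNA was extracted, made into libraries and sequenced by a commercial service from pools of cells. How many cells a pool held, how they were collected and from which host is not given in the sources used here, nor are the library kit, strandedness, aligner, read counter and annotation. The submitters' processing notes name the genome build hg18. The deposited signal is a table of normalized counts, in which the authors divided each library's gene counts by 1 factor; the program is not given in the sources used here.

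Each library's values were whole multiples of 1 step, the worth of 1 read, which ranged from 0.606 to 1.75 normalized counts. Dividing by it gave whole numbers, within 0.001 of a read, for 100% of values in each library. The factors recovered this way differed from DESeq2's median-of-ratios size factors, computed on the recovered reads of the tested genes, by at most 0.120%. Read totals over the table ranged from 18278787 to 49661996, and 3 reads in a library corresponded to 1.82 to 5.26 normalized counts. Gene identifiers were joined to symbols by identifier, and 17364 of 19604 had one. Positions in the genome are not given, because the reference annotation at hand belongs to another build. The recovered reads of replicate pairs within a group differed by more than sampling noise, with chi-square per degree of freedom from 9.75 to 122, so no library was counted as a copy of another.

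Genes with a mean of at least 10 normalized counts over the 6 libraries were tested on log2(normalized count + 1) with limma (version 3.58.1, R 4.3.3), with a mean-variance trend, robust moderation, no covariates and two-sided p-values adjusted by Benjamini-Hochberg, at a threshold of 0.05. A count test was an alternative, since the table holds normalized values. Gene lists were tested with camera in limma at its preset correlation of 0.01, over the 45 of 47 fixed lists that had at least 5 tested members. The lists held 1194 distinct genes, of which 997 had a value. Beside the preset, camera was run with an estimated correlation, and fry tested whether a list's genes moved one way without comparing them with other genes. In 3 of the tested lists some members had 0 reads in a whole group; with these at the bound given by 3 reads over the group, the list medians moved by 0.

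The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 largest rises and 12 largest falls on the log2 scale among genes with an adjusted p under 0.05, a mean of at least 50 normalized counts, groups that did not overlap and a symbol that is not a clone, LOC, open reading frame, pseudogene or small RNA name. It added up to 4 members of each described list with the smallest p among those with a mean of at least 50, or of at least 10 where fewer than 2 reached 50, and 10 genes whatever their values: MITF, SOX10, PMEL, MLANA, AXL, VIM, CDH2, MKI67, CCND1 and VEGFA. Genes outside the rule were chosen after their values were seen: some members where 5 or fewer of a list were called (ATF3, MANF, SDF2L1, HSPA5, FKBP4, GADD45A, IRF1, S100A4, FOXC2, TGFBI, TNC, IL6, CCL2, BIRC2, ANKRD37, PFKFB4, HK1, ACTA1, RBFOX3, CD4 and ACTA2) and the family members and BST2 in the closing section. NFKB2, ICAM1 and SAA1, members of the NF-kappaB list that fell, were also chosen after their values were seen.

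Alternatives were pseudocounts of 0.5 and 8, no filter or a mean of at least 50, upper-quartile, TMM and quantile scaling, sample quality weights, a replicate block, edgeR (4.0.16) quasi-likelihood and DESeq2 (1.42.0) tests on the recovered reads, a 2-fold minimum, and leaving out each library in turn. Thinning to the reads of the shallowest library and 1 variance weight per group were added after the data had been seen. On recovered reads, edgeR called 1468 genes higher and 1782 lower. The gene test was checked on simulated counts drawn from the real means and depths for extravasating against control, over 18688 genes: it found 10.6% of genes changed by log2 1, 65.7% of those changed by log2 2 and 89.6% of those changed by log2 4, and called 0.005% of unchanged genes. A simulated list that moved had a camera adjusted p of 3.26e-24 and 0 of 45 unchanged lists were called. Only 200 simulated genes and the list that moved were changed, whereas 33.7% of genes in the real comparison had an unadjusted limma p under 0.05. The Benjamini-Hochberg adjustment was therefore stricter in the simulation. Its detection rates and its share of unchanged genes called need not hold for the real comparison. Simulated genes were drawn independently of each other, so this cannot show how the list test behaves when members of a list are correlated. Figures were drawn with matplotlib 3.10.9.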

Results

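RNA sequencing measured transcript levels in A375 cells, a human melanoma line that grows under an activating BRAF mutation. The cells stably expressed EosFP, a fluorescent protein whose colour can be switched with light. Per the labels, 3 libraries came from extravasating cells, tumour cells leaving a vessel, and 3 from control cells. The series title names the route as angiopellosis, in which the vessel wall is remodelled around the leaving cells. The comparison asked how transcripts in the extravasating cells differed from those in the control cells. Over the 19604 genes of the table, the control libraries held 40932915, 49661996 and 45250861 reads and the extravasating libraries 22339820, 18278787 and 25973080. In the control libraries 64, 57 and 96 genes were listed at 0 reads, and in the extravasating libraries 917, 1157 and 794. Log2 values correlated across genes between 0.983 and 0.992 among control libraries, between 0.866 and 0.909 among extravasating libraries and between 0.858 and 0.895 across the groups. The median gene had an SD of 0.17 log2 units among control libraries and 0.51 among extravasating libraries. Genes are not independent replicates in these correlations. Means below are given as mean ± SD normalized counts over n = 3 libraries per group, and log2 changes are extravasating minus control on the log2(normalized count + 1) scale. The added 1 understates changes of low genes, but where only some libraries of a group are at 0 reads the log2 change can exceed the change of the means.

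**Figure D1:**
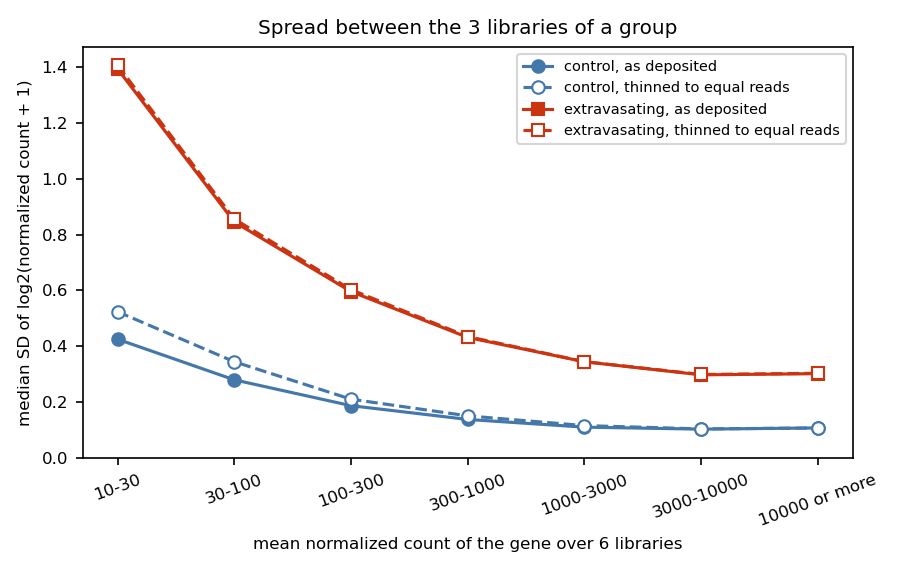
Median over genes of the SD of log2(normalized count + 1) between the 3 libraries of a group (vertical axis), by the gene's mean normalized count over 6 libraries (horizontal axis); filled symbols show the deposited values and open symbols libraries thinned to equal reads. The extravasating libraries lay above the control libraries in each of the 7 ranges, at 1.40 against 0.42 for genes between 10 and 30 and at 0.30 against 0.11 for genes of 10000 or more.

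In extravasating cells, camera at its preset correlation called the immediate early, heat shock, DNA replication and mitosis lists higher and the interferon response, extracellular matrix and integrin lists lower. The histone list, fixed as a sign of RNA quality and normalization, was also called higher. With an estimated correlation none of these lists passed (adjusted p from 0.154 to 0.796), and the matrix list was not called without extravasating replicate 1 (adjusted p = 0.0803). HSPA6 (ENSG00000173110), a strictly inducible member of the HSP70 chaperones, rose from 237 ± 11.02 to 65166 ± 46969 (log2 change 7.67 ± 0.68 SE, limma adjusted p = 0.00140). DKK1 (ENSG00000107984), a secreted Wnt antagonist, rose from 119 ± 66.1 to 9203 ± 2723 (log2 6.35 ± 0.41 SE, limma adjusted p = 0.000582), and NGFR (ENSG00000064300), a neurotrophin receptor that marks neural crest-like melanoma cells, from 11.6 ± 8.38 to 1038 ± 347 (log2 6.50 ± 0.52 SE, limma adjusted p = 0.00108). PDE3A (ENSG00000172572), a cyclic nucleotide phosphodiesterase, fell from 2538 ± 431 to 67.7 ± 55.7 (log2 change -5.99 ± 1.01 SE, limma adjusted p = 0.00943). ITGA1 (ENSG00000213949), the collagen-binding alpha-1 integrin subunit, fell from 19419 ± 875 to 3071 ± 176 (log2 change -2.66 ± 0.12 SE, limma adjusted p = 0.000348).

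Of 19227 genes tested with limma, 1556 were higher and 1816 lower in extravasating cells at an adjusted p under 0.05, and 1072 and 1358 of these changed at least 2-fold. In each of the 3372 called genes all 3 extravasating libraries lay on the same side of all 3 control libraries. This held for 8028 of the tested genes, or 41.8%, where chance gives 10% for 3 against 3 if both groups vary alike, and 13.9% for simulated normal values with the median SDs of the 2 groups. The median change over all tested genes was -0.09. Nothing in the labels says that libraries of a group came from separate cultures or animals, so p-values measure only the spread between these samples. Leaving out a control library left 445 higher and 438 lower genes (without control replicate 1), 435 and 402 (replicate 2) or 614 and 589 (replicate 3), while leaving out extravasating replicate 1 gave 2489 and 2980. The limma fit takes 1 variance per gene over both groups, whose median SDs were 0.17 (control) and 0.51 (extravasating). With unequal group sizes it tends to be too small without an extravasating library and too large without a control library. Passes named below for runs without an extravasating library are therefore lenient. With DESeq2 on the recovered reads, 2607 genes were higher. Of 132 called genes named in the text, leaving out control replicates 1, 2 and 3 ended 50, 53 and 44 calls, and leaving out extravasating replicates 1, 2 and 3 ended 5, 16 and 7. These counts, and those over genes and settings in the closing sections, leave out NFKB1, NFKB2, ICAM1 and SAA1.

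The 12 named genes with the largest rises spanned log2 changes from 6.22 to 7.67. They included the metalloproteinases MMP10 and MMP3, which cleave matrix proteins such as proteoglycans. MMP10 had 1 control read against 546 extravasating reads, a ratio of 1146 after normalization (95% counting interval 206 to 45259.5), and MMP3 had 3 against 252, a ratio of 176 (60.3 to 855). ARL14, a small GTPase, had 0 control reads and 175 ± 91.3 normalized counts in extravasating cells, at least 246-fold higher when the floor is 3 reads over the control group. NAV3, a microtubule-associated neuron navigator, rose from 4.33 ± 5.85 to 688 ± 429, and TRIML2 from 5.56 ± 2.26 to 596 ± 197. The others were HSPA6, DKK1, NGFR, B3GALT5, ANKRD1 and the non-coding LINC03061 and LINC00702. Counting intervals and floors cover counting error only.

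Among the 12 largest falls, log2 changes ran from -5.51 to -6.94. Where some extravasating libraries had 0 reads, the log2 change could be larger than the change of the means. For MAT1A it stood for a 53.4-fold fall, while the extravasating mean was 0.107 times the control mean. For FBLN5 these values were 114-fold and 0.0642 times. SPTSSB, a small subunit of serine palmitoyltransferase, went from 122 ± 8.61 to 0 reads in the extravasating libraries, at least 85.6-fold lower with the floor of 3 reads over the group. PCDH18, a protocadherin, had 941 control reads and 3 extravasating reads, so that controls were higher by a ratio of 149 (95% counting interval 51.1 to 725). FGF7, a fibroblast growth factor, fell from 97.6 ± 20.3 to 2.92 ± 5.06, and IGFBP5, which binds insulin-like growth factors, from 200.6 ± 35.4 to 9.46 ± 16.4. The remaining genes were FBLN5, CES5A, LINC02289, PDE3A, ASAP3, ACSM3, MAT1A and RASAL1. Leaving out 1 extravasating library ended the limma calls of FBLN5 (adjusted p = 0.0588 without replicate 1 and 0.0923 without replicate 2), IGFBP5 (0.0582 without replicate 2), ASAP3 (0.0543 without replicate 2), ACSM3 (0.0745 without replicate 1 and 0.0979 without replicate 3) and MAT1A (0.0812 without replicate 1 and 0.120 without replicate 2). Over the alternatives run, adjusted p ranged from 0.00137 to 0.242 for FBLN5, from 0.00117 to 0.0921 for IGFBP5, from 0.000597 to 0.147 for ASAP3, from 0.00329 to 0.317 for ACSM3 and from 0.00196 to 0.338 for MAT1A.

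**Figure D2:**
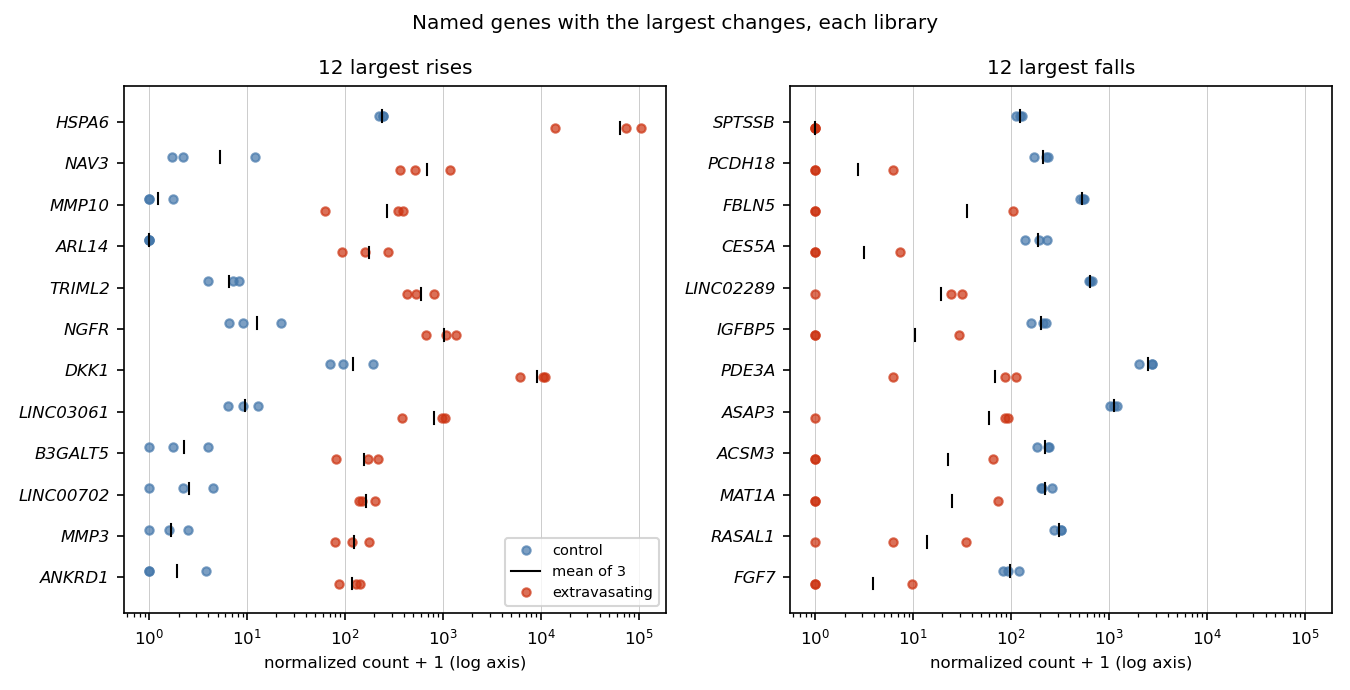
Normalized count + 1 on a log axis in each library for the 12 named genes with the largest rises and the 12 with the largest falls; blue points are control libraries, red points extravasating libraries and black bars the means of 3. In each gene the 3 extravasating libraries lay on one side of the 3 control libraries, with HSPA6 between 14138 and 106593 in extravasating cells.

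Immediate early genes, transcribed within minutes of a stimulus, had the smallest p of the lists in camera at the preset correlation: 17 of 33 members rose and 0 fell, with a median log2 change of 2.11 (camera adjusted p = 7.64e-08; adjusted p = 0.509 with an estimated correlation). Adjusted over the list alone, 22 rose and 1 fell. EGR1, a growth factor-induced transcription factor, rose from 289 ± 97.3 to 4052 ± 212, JUN, a subunit of AP-1, from 108 ± 36.8 to 1496 ± 156, and KLF6 from 943 ± 43.1 to 8037 ± 2118. PPP1R15A, which directs dephosphorylation of eIF2alpha and also belongs to the unfolded protein list, rose from 2242 ± 116 to 26477 ± 8560. List medians against the control mean were 1.26, 2.30 and 1.79 in extravasating libraries 1, 2 and 3. The unfolded protein and amino acid stress list was not called: 5 of 30 members rose and 6 fell, with a positive median of 0.05 and test and a negative mean of -0.10 (camera adjusted p = 0.907), or 5 and 8 adjusted over the list alone. The members that rose were PPP1R15A, ATF3, MANF, SDF2L1 and the chaperone HSPA5. Among those that fell, PSAT1 and SHMT2, enzymes of serine and glycine metabolism, went from 24237 ± 1809.5 to 10437 ± 1214 and from 15798 ± 1132 to 6109 ± 1984, and XBP1, a transcription factor of the unfolded protein response, from 14356 ± 1112 to 7747 ± 569.8.

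Heat shock genes, which encode chaperones and their cofactors, had 10 of 22 members higher and 1 lower, with a median log2 change of 1.14 (camera adjusted p = 1.91e-06; adjusted p = 0.796 with an estimated correlation). Adjusted over the list alone the counts were 13 and 1. FKBP4 was the member that fell. HSPA1A rose from 631 ± 36.9 to 19089 ± 7372 and HSPA1B from 588 ± 103 to 16090.2 ± 6739. These 2 genes encode nearly the same protein from nearly the same sequence, as HSPA6 does with a neighbouring pseudogene, so the split of reads between copies is uncertain. DNAJB4, an HSP40 cofactor, rose from 681 ± 77.0 to 6831 ± 2146. The list's median differed between extravasating libraries, at 0.35, 1.85 and 1.20.

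In the DNA replication and G1/S list 10 of 28 members rose and 0 fell, with a median log2 change of 0.92 (camera adjusted p = 2.62e-06; adjusted p = 0.796 with an estimated correlation), and 16 rose adjusted over the list alone. PCNA, the sliding clamp of DNA polymerases, rose from 3311 ± 331 to 7328 ± 198, GINS2, a part of the replicative helicase, from 442 ± 104 to 1869 ± 416, and MCM4 and UHRF1 also rose. In the mitosis and G2/M list 8 of 30 rose and 0 fell, with a median of 1.09 (camera adjusted p = 4.65e-06; adjusted p = 0.796 with an estimated correlation), or 9 adjusted over the list alone. CCNA2, cyclin A2, rose from 608 ± 103 to 3144 ± 1366 and UBE2C, an enzyme of the anaphase-promoting pathway, from 1189 ± 185 to 7983 ± 5317, and ANLN and KIF11 rose as well. The mitosis median was 0.11 in extravasating library 1 against 1.498 and 1.80 in the other libraries. MKI67, a proliferation marker, was at 355 ± 71.1 and 718 ± 265 and did not pass (log2 0.95 ± 0.34 SE, limma adjusted p = 0.0979); it passed without extravasating replicate 1 (log2 1.31, adjusted p = 0.00898) and with DESeq2, over a range from 0.00898 to 0.263. Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, had 7 of 21 members higher and 0 lower, with a median of 1.18 (camera adjusted p = 6.30e-05; adjusted p = 0.502 with an estimated correlation), or 9 adjusted over the list alone. The histone list had been fixed as a sign of RNA quality and normalization, not of the cell cycle. Its median was 1.59, 0.84 and 1.03 in extravasating libraries 1, 2 and 3, and 0.75 without replicate 1. Library 1 was thus highest for histones but lowest for mitosis and for DNA replication, whose medians were 0.47, 1.09 and 1.17. H4C3 rose from 4546 ± 182 to 16450.0 ± 7181. H2BC9 and H3C10 rose too, but histone genes are near-identical copies, and their shares of reads are uncertain. In the list of CDK inhibitors and p53 targets 1 of 24 rose and 4 fell, with a median of -0.48 (camera adjusted p = 0.159), or 1 and 6 adjusted over the list alone. SESN1, a p53-induced sestrin, fell from 781 ± 52.0 to 161 ± 70.9, as did ZMAT3, RRM2B and FDXR, and GADD45A rose.

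Interferon response genes were lower: 15 of 42 members fell and 1 rose, with a median log2 change of -1.30 (camera adjusted p = 1.91e-06; adjusted p = 0.154 with an estimated correlation). Adjusted over the list alone, 19 fell and 2 rose. IRF1, a transcription factor of the pathway, was the member that rose. GBP2, an interferon-induced GTPase, fell from 3580.1 ± 377 to 524 ± 71.6, and MX1, an antiviral GTPase, from 1891 ± 105 to 385 ± 62.4. STAT2, which carries the type I interferon signal to the nucleus, fell from 3819 ± 284 to 1291 ± 148, and PARP9 from 2211 ± 84.4 to 610 ± 169. Median deviations were -1.01, -0.89 and -1.22 in extravasating libraries 1, 2 and 3. Antigen presentation genes followed in the same direction, with 9 of 28 lower and 0 higher and a median of -0.47 (camera adjusted p = 0.00357; adjusted p = 0.796 with an estimated correlation), and the same counts adjusted over the list alone. HLA-F fell from 694 ± 61.5 to 203 ± 20.8, HLA-C from 16009 ± 919 to 7995 ± 1693 and the loading factor TAPBP from 10422 ± 1209 to 5191 ± 776. HLA genes share reads with their relatives, which leaves their separate levels uncertain. Its median was -0.94, -0.43 and -0.02 in extravasating libraries 1, 2 and 3, and -0.77 without replicate 3. Without extravasating replicate 1 it was -0.17 and the list was no longer called (camera adjusted p = 0.183; range over the alternatives 0.000121 to 0.183).

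In the extracellular matrix list 18 of 38 members fell and 2 rose, with a median log2 change of -0.996 (camera adjusted p = 0.00393; adjusted p = 0.796 with an estimated correlation), or 21 and 3 adjusted over the list alone. LOXL4, a lysyl oxidase that crosslinks collagen, fell from 49825 ± 1618 to 5593 ± 2458. LAMA4 and LAMA5, laminin alpha chains of basement membranes, fell from 13516 ± 1296 to 3635.5 ± 446 and from 2268 ± 173 to 327 ± 128. THBS1, a thrombospondin that inhibits angiogenesis, went the other way, from 3033 ± 476 to 33241 ± 8591. Without extravasating replicate 1 the matrix list was not called (camera adjusted p = 0.0803; range over the alternatives 0.000483 to 0.0803). Integrins, the receptors that bind cells to that matrix, had 6 of 19 members lower and 0 higher, with a median of -0.96 (camera adjusted p = 0.00987; adjusted p = 0.475 with an estimated correlation), or 7 lower adjusted over the list alone. Besides ITGA1, ITGA5, the fibronectin receptor's alpha subunit, fell from 14830.5 ± 780.1 to 5085 ± 1159, ITGB3 from 5234 ± 988 to 1229 ± 450.1 and ITGA9 from 560 ± 127 to 67.2 ± 37.2.

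The list of matrix proteases and their inhibitors was not called, with 6 of 37 members higher and 6 lower (camera adjusted p = 0.543), or 6 and 8 adjusted over the list alone. Its median was -0.48 and its test ran the same way, while its mean was 0.16, of opposite sign. MMP1, an interstitial collagenase, rose from 39.4 ± 20.4 to 1424 ± 839, while MMP8, a neutrophil-type collagenase, fell from 1245 ± 138 to 425 ± 24.9. Among mesenchymal genes 7 of 22 fell and 3 rose, with a median of -0.64 (camera adjusted p = 0.197), or 9 and 3 adjusted over the list alone. The mesenchymal list did pass with fry, which makes no comparison with other genes (fry adjusted p = 0.000485). SNAI2, the transcription factor Slug, fell from 1808 ± 73.3 to 272 ± 98.9, ZEB1 from 2385 ± 95.7 to 896 ± 338 and the matrix protein POSTN from 1855 ± 174 to 664 ± 139. VIM, the intermediate filament vimentin, rose from 16019.8 ± 454 to 31446 ± 7966, and S100A4 and FOXC2 rose too. CDH2, N-cadherin, was at 3142 ± 96.8 and 2865 ± 876 and did not pass (log2 -0.17 ± 0.22 SE, limma adjusted p = 0.616).

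YAP and TEAD target genes, read-outs of mechanical and Hippo signalling, had 7 of 26 members higher and 0 lower with a median log2 change of 0.62 (camera adjusted p = 0.00526; adjusted p = 0.475 with an estimated correlation), or 8 higher adjusted over the list alone. CCN1, a secreted matricellular protein, rose from 402 ± 59.7 to 13650.4 ± 6820.3, GADD45B, a stress sensor, from 109 ± 6.31 to 4486 ± 1270 and the membrane repair protein MYOF from 681 ± 113 to 3662 ± 770. CCN1 also belongs to the immediate early list. In the list of dedifferentiated or invasive melanoma genes 10 of 25 rose and 4 fell, with a median of 0.72 (camera adjusted p = 0.00537; adjusted p = 0.502 with an estimated correlation), or 12 and 4 adjusted over the list alone. Its members THBS1, JUN, CCN1 and NGFR are named above and belong to other lists too. The list's median was 1.33 without extravasating replicate 1. The members that fell were TGFBI, PDGFRB, TNC and ZEB1. AXL, a receptor tyrosine kinase of that state, was at 3765 ± 681 and 3449 ± 1175 and did not pass (log2 -0.17 ± 0.27 SE, limma adjusted p = 0.704).

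The melanocyte differentiation list was not called: 0 of 19 members rose and 3 fell, with a median of -0.01 (camera adjusted p = 0.798), and the same counts adjusted over the list alone. EDNRB, the endothelin B receptor, fell from 4338 ± 18.9 to 910.0 ± 146, APOE from 260.4 ± 36.7 to 46.1 ± 15.3 and MREG from 398 ± 103 to 140 ± 51.5. MITF, the master regulator of this lineage, was at 1126 ± 105 and 1050.2 ± 333 (log2 -0.15 ± 0.27 SE, limma adjusted p = 0.730), and MLANA was low in both groups, at 19.5 ± 5.43 and 22.2 ± 19.5. PMEL was at 36.7 ± 8.37 and 249.7 ± 206 and did not pass (log2 1.96 ± 1.04 SE, limma adjusted p = 0.230); without extravasating replicate 1 it passed (log2 3.28, adjusted p = 0.00262), as it did with DESeq2 and with sample quality weights, over a range from 0.00262 to 0.481. SOX10 was not analysed here. CCND1, cyclin D1, was at 8438 ± 356 and 9228 ± 1739 (log2 0.11 ± 0.16 SE, limma adjusted p = 0.667).

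NF-kappaB target genes divided, 5 of 32 rising and 6 falling with a median of -0.05 (camera adjusted p = 0.798), or 6 and 8 adjusted over the list alone. The cytokine IL1A fell from 3304 ± 180 to 169 ± 61.0 and complement C3 from 10353 ± 1868 to 2301 ± 754. NFKB1 fell from 9748 ± 1915 to 3443 ± 823, and NFKB2, ICAM1 and SAA1 fell too. The cytokine CSF2 rose from 10.8 ± 3.78 to 441 ± 458, as did CCL2, IL6, BIRC2 and IRF1. Hypoxia response genes had 3 of 29 higher and 3 lower with a median of -0.43 (camera adjusted p = 0.555), or 3 and 5 adjusted over the list alone. ADM, the vasodilator adrenomedullin, rose from 290.1 ± 13.9 to 2353 ± 753, SLC2A1, a glucose transporter, from 2911 ± 121 to 6321 ± 905, and VEGFA, the main angiogenic growth factor, fell from 3992 ± 101 to 1914 ± 305. ANKRD37 rose too, and PFKFB3 and PFKFB4 fell. Glycolysis genes had 1 of 22 higher and 4 lower with a median of -0.12 (camera adjusted p = 0.555), or 2 and 5 adjusted over the list alone; PFKM, muscle phosphofructokinase, fell from 4529 ± 101 to 1813 ± 40.2, as did HK1, ENO2 and PFKFB3. In oxidative phosphorylation 0 of 42 members changed at an adjusted p under 0.05 in limma, and 0 adjusted over the list alone (median 0.20, camera adjusted p = 0.264); 7 had an unadjusted p under 0.05, edgeR called 0 and DESeq2 1.

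Markers of other cell types and signs of RNA quality were read in the same libraries. Of the fixed markers, 9 of 23 for muscle, 8 of 17 for keratinocytes and epithelium and 10 of 22 for endothelium could be tested. For leukocytes these were 9 of 24, for neurons and glia 11 of 20 and for fibroblasts and pericytes 14 of 19. The rest had no value or a mean under 10 normalized counts. Skeletal and cardiac muscle markers had 2 of 9 tested members higher and 0 lower, with a median log2 change of 1.43 (camera adjusted p = 0.00537; adjusted p = 0.540 with an estimated correlation), or 3 higher adjusted over the list alone. ACTN2, sarcomeric alpha-actinin, rose from 79.1 ± 12.3 to 483 ± 169, and so did ACTA1. Keratinocyte and epithelial markers had 4 of 8 higher and 0 lower, with a median of 0.66 (camera adjusted p = 0.0363; adjusted p = 0.502 with an estimated correlation), and the same counts adjusted over the list alone. KRT14, a basal epidermal keratin, rose from 6.56 ± 3.71 to 347 ± 125, KRT15 from 17.3 ± 7.38 to 243 ± 42.2 and KRT10 from 3109 ± 374 to 7476 ± 1091, and KRT18 rose too. Without extravasating replicate 1, 2 or 3 the median was 1.16, 0.51 and 0.40 and the list was not called (camera adjusted p = 0.0663, 0.0640 and 0.108; range over the alternatives 0.0135 to 0.108). With all 6 libraries the keratinocyte call also ended under sample quality weights, the replicate block and 1 variance weight per group (camera adjusted p = 0.0914, 0.0559 and 0.0663). Endothelial markers were not called (1 of 10 higher, 0 lower, median -0.57, camera adjusted p = 0.680), nor leukocyte markers (1 of 9 higher, 1 lower, median 1.06, camera adjusted p = 0.525), nor neuron and glia markers (1 of 11 higher, 1 lower, median -0.68, camera adjusted p = 0.543). Adjusted over each list alone, these counts were 1 and 1, 2 and 1, and 1 and 1. The endothelial member that rose was ROBO4, and of the others RBFOX3 rose and CD4 fell. LCP1, the leukocyte actin bundler, rose from 138 ± 9.98 to 465 ± 82.4. CD163, a macrophage scavenger receptor, had 0 reads in the control libraries and 0, 186 and 199 normalized counts in extravasating libraries 1, 2 and 3. That is at least 182-fold higher with the floor of 3 reads over the control group, but it did not pass (limma adjusted p = 0.138, range over the alternatives 0.00150 to 0.308). Among the alternatives, CD163 passed without extravasating replicate 1 (limma adjusted p = 0.00150) and with DESeq2 on all 6 libraries. CSF1R, the macrophage growth factor receptor, was at 24.2 ± 2.10 and 82.3 ± 43.8 and did not pass (limma adjusted p = 0.0554, range over the alternatives 0.0118 to 0.192). Among the alternatives, CSF1R passed without extravasating replicate 3 (limma adjusted p = 0.0285) and with DESeq2 on all 6 libraries. Fibroblast and pericyte markers had 0 of 14 higher and 5 lower (median -1.04, camera adjusted p = 0.433), and the same counts adjusted over the list alone; CSPG4, which melanoma cells also express, fell from 25159 ± 5754 to 5365 ± 2819, as did PDGFRB, ACTA2, C1S and C1R.

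Ribosomal protein genes had 12 of 74 members higher and 0 lower, with a median of 0.45 (camera adjusted p = 1.28e-07; adjusted p = 0.796 with an estimated correlation), or 20 higher adjusted over the list alone. Its median was 0.29 without extravasating replicate 3. RPLP0, a protein of the ribosomal stalk, rose from 27361 ± 738 to 48173 ± 11349. Mitochondrially encoded genes took 3.37%, 3.63% and 2.44% of reads in the control libraries and 4.05%, 1.25% and 2.36% in the extravasating libraries, and 0 of 13 changed at an adjusted p under 0.05 in limma (median -0.43, camera adjusted p = 0.523), as adjusted over the list alone, at an unadjusted p under 0.05, with edgeR and with DESeq2. Housekeeping reference genes had 3 of 18 higher and 2 lower with a positive median of 0.12 and test and a negative mean of -0.02 (camera adjusted p = 0.749), the same counts as adjusted over the list alone. ACTB, beta-actin, rose from 110036 ± 7797 to 227646 ± 53344, and B2M, the light chain of HLA class I, fell from 113495 ± 9227 to 71370.2 ± 7719. RPLP0 and YWHAZ rose and IPO8 fell. None of the 14 called lists passed with an estimated correlation, where 3 of 45 lists had an unadjusted p under 0.05. With fry 9 of the 14 passed; the DNA replication, mitosis, antigen presentation, extracellular matrix and ribosomal protein lists did not (fry adjusted p = 0.0624, 0.143, 0.108, 0.0617 and 0.112). A split of the 6 libraries that put 2 control libraries and 1 extravasating library on one side also called 14 lists with camera. Such a split still holds part of the group difference, so it cannot tell whether the list calls arose by chance.

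**Figure D3:**
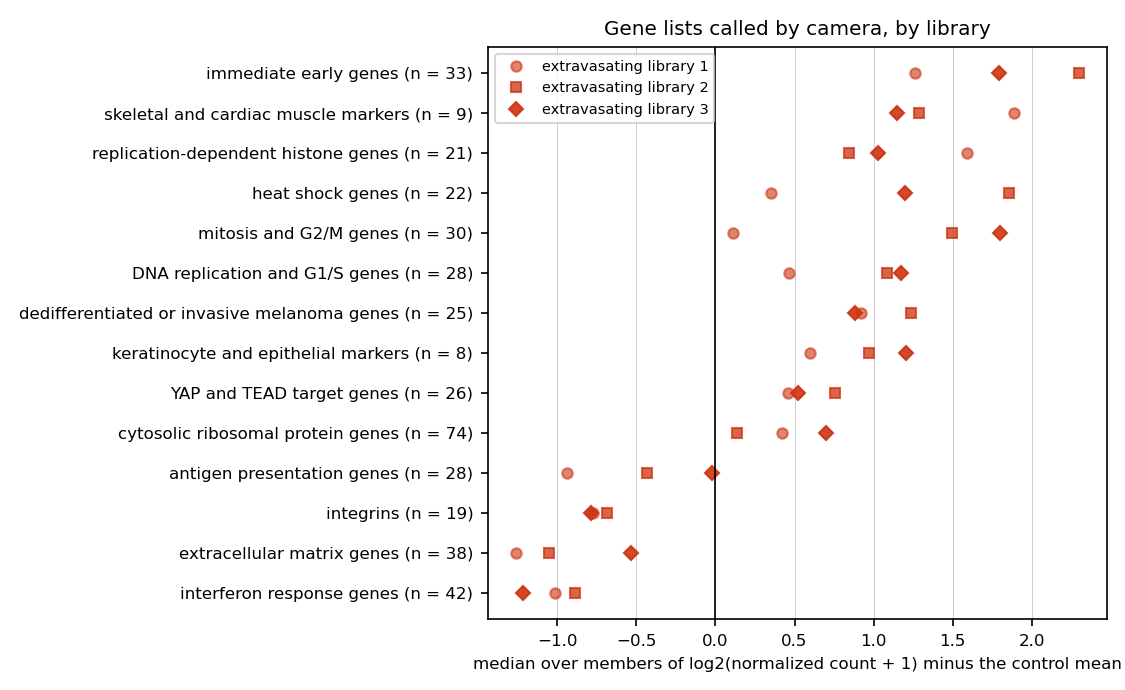
Median over list members of log2(normalized count + 1) minus the control mean (horizontal axis), for each of the 14 lists that camera called (vertical axis, with the number of tested members); each symbol is 1 of the 3 extravasating libraries and the line at 0 is the control mean. Immediate early genes lay at 1.26, 2.30 and 1.79 and interferon response genes at -1.01, -0.89 and -1.22.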

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

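The tests with thinned reads and with group variance weights were chosen after the data had been seen. With all 6 libraries, the counts of higher (1556) and lower genes (1816) stayed within 1.5 times in the alternatives other than DESeq2, with 2607 higher. Leaving out 1 library gave 435 to 2489 higher and 402 to 2980 lower genes. A single variance per gene over groups of unequal spread would raise the counts without an extravasating library and lower them without a control library. Without extravasating replicate 2, however, 1347 were higher and 1810 lower, and how far the variance accounts for the counts was not tested. For lists, 13 to 15 were called in other runs of camera and 0 with an estimated correlation. For the interferon response, integrin, YAP and keratinocyte lists the estimated correlation was -0.00787, -0.0237, -0.0222 and -0.0883, below the preset of 0.01. Correlation between members therefore does not account for the calls lost by those lists. In the other called lists it ranged from 0.0429 to 0.808. Fry called 11, of which 9 were among the 14 and 5 of the 14 lost the call. Its other calls were the mesenchymal and angiogenic lists (fry adjusted p = 0.000485 and 0.0460). Replicate numbers did not pair the samples (correlations of same-numbered deviations 0.117, -0.0959 and 0.0229); with the replicate block 1090 genes were higher, 1398 lower and 13 lists called. The share of calls that were higher was 46.1%, and 55.5% with upper-quartile scaling. Of the genes named, 4 that were not called changed sign, and the cause was not tested: MITF with sample quality weights (0.00881) and over left-out libraries (-0.34 to 0.14), MLANA with edgeR (0.16), DESeq2 (0.20), thinning (0.11) and left-out libraries (-0.80 to 0.45), CCND1 (-0.0276 to 0.241) and AXL (-0.415 to 0.0851) over left-out libraries. Over genes and settings, 2456 comparisons kept direction and side of the threshold, 215 lost the call, 13 gained it and 8 changed sign; over lists 238 held and 27 lost the call. Depth limits genes near the floor of 1.82 to 5.26 normalized counts.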

Other observations

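The tests on gene families, thinned reads, genes at 0, abundant genes, scaling and handling were chosen after their results had been seen. Families were defined by the letters of gene symbols, and their members named here were chosen after their values were seen. Of 168 families with at least 10 tested members, 17 had a camera adjusted p under 0.05, 9 higher and 8 lower, and 0 passed with an estimated correlation, where 6 had an unadjusted p under 0.05. Small nucleolar RNA host genes had 11 of 23 members higher and 1 lower (median log2 change 0.75, camera adjusted p = 0.000909; adjusted p = 0.770 with an estimated correlation). SNHG15 rose from 880.3 ± 15.3 to 4252 ± 376 and SNHG17 from 4399.5 ± 233 to 15269 ± 751, while SNHG14, a long transcript of an imprinted region, fell from 4363 ± 632 to 1288 ± 343. Keratins had 7 of 15 members higher and 0 lower (median 1.26, camera adjusted p = 0.00177; adjusted p = 0.770 with an estimated correlation). KRT80 rose from 126 ± 7.42 to 2287 ± 1108, and KRT34, a hair keratin, had 1 control read against 87.2 ± 33.7 normalized counts. Protocadherin beta genes, clustered adhesion molecules, had 0 of 16 members higher and 8 lower (median -1.58, camera adjusted p = 0.00334; adjusted p = 0.770 with an estimated correlation). PCDHB5 fell from 679 ± 43.4 to 180.5 ± 64.4 and PCDHB7 from 541 ± 51.4 to 118 ± 57.9, although reads shared between such similar genes leave each level uncertain. Splicing factors of the SRSF family had 5 of 12 higher and 0 lower (median 0.68, camera adjusted p = 0.0196; adjusted p = 0.770 with an estimated correlation), with SRSF3 rising from 8307 ± 295 to 18524 ± 2455 and SRSF2 from 5096 ± 97.1 to 9593 ± 1420. RGS2, a brake on G protein signalling, rose from 702 ± 127 to 9433 ± 2996.

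The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division called 3372 genes, as many as 1 of the 10 splits counting itself, and the highest other split called 0 with limma, where the highest count at an unadjusted p under 0.05 was 1004. Each other split mixed the groups on both sides, which puts the group difference into the spread within a side. Its 0 calls are therefore not a count for groups without a difference. For lists the real division called 14 and the highest other split 14, so that 2 of the 10 splits gave as many. That other split set control 1, control 2 and extravasating 1 apart, which leaves part of the group difference between its sides. The tie therefore cannot tell whether the list calls arose by chance.

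The extravasating libraries differed from each other more than the control libraries did. With every library thinned to the 18278787 reads of the shallowest, the median SD was still 2.71 times that of the controls, against 2.96 times as deposited, which argues against sequencing depth as the whole cause. A library made from few RNA molecules loses weakly expressed genes at random: 20 genes with a control mean of 100 or more had 0 reads in exactly 1 extravasating library and at least 50% of the control mean in the other 2, among them BST2 at 0, 205 and 254, while 0 genes did so among controls, consistent with few starting molecules for such genes. Few molecules alone would let the spread shrink with expression, but above 10000 normalized counts the median SD was 1.01 times (bootstrap interval over genes 0.943 to 1.09) that between 3000 and 10000, which argues against it as the only cause for abundant genes. The bootstrap drew genes of the same libraries, so its interval does not cover the spread between pools. The control libraries were flat over these ranges too, with median SDs of 0.106 and 0.102. Real differences between pools of extravasating cells, or in how each was collected, stay open and were not tested.

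The medians of the immediate early and heat shock lists were higher in extravasating cells. Reads shared between near-identical heat shock genes do not account for it, since the list's median was 1.01 without HSPA1A, HSPA1B, HSPA1L, HSPA6 and HSPA8, against 1.14 with them, and camera still called it at the preset correlation (adjusted p = 0.000336; adjusted p = 0.796 with an estimated correlation). Scaling of the libraries or a few abundant genes do not either, as under 3 other scalings the immediate early median was at least 2.07 and the heat shock median at least 1.096. Handling of the cells during collection, which induces both groups within minutes to hours, may have contributed: both medians exceeded those of the controls in 3 of 3 extravasating libraries, which a response to leaving the vessel would show as well, so the 2 cannot be told apart in a design where collection and group coincide.

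The medians of the interferon response, extracellular matrix and integrin lists were lower in extravasating cells. Loss of weakly expressed genes from low-input libraries could lower log means. Of 10000 random lists matched on mean expression, 0 had a median as low, so the interferon response, extracellular matrix and integrin lists each lay at percentile 0. The 1st percentiles of the random medians were -0.43, -0.43 and -0.58, against observed medians of -1.30, -0.996 and -0.96. The antigen presentation list, with a median of -0.47, lay at percentile 0.25. Camera at its preset correlation had called these lists lower than other genes, so the percentiles repeat part of that comparison. Random lists of separately drawn genes also lack the correlation within a list. The percentiles show only that a list's mean expression did not account for its median. A change of programme in cells that leave the vessel remains an untested hypothesis, and so do differences in culture between the groups.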
